A study of Homo sapiens with 6 samples.

How the data were processed

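Anti-HA ChIP-seq of HA-METTL14 was analysed in 6 libraries of HepG2 cells. They were 2 IP and 2 input libraries of untreated cells and 1 IP and 1 input library of cells given 100 µM DRB for 3 h. Per the labels' protocols, the tagged METTL14 was introduced by lentivirus with puromycin selection and sorting for GFP, chromatin was sheared by sonication, 2 µg of antibody was used, and single-end reads of 50 nt were produced. Nothing in the labels says whether the 2 untreated libraries came from separate cultures.

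The submitters' processing notes name FastQC 0.11.5, Bowtie 1.1.2, SICER without a version, and the genome build hg19. SICER's window, gap and redundancy settings are not given in the sources used here, nor is the way the 2 untreated replicates were combined. From the values, all islands are whole multiples of 200 bp and lie at least 800 bp apart. Each condition came as 1 table of candidate islands with IP reads, input reads, p-value, fold and false discovery rate (FDR), and 1 list of significant islands with positions only. The files have no headers, so the column meanings were tested on the values. The deposited counts are whole numbers of reads per island for the IP and for the input, not normalized. The deposited fold, a ratio, equals IP reads over input reads times a constant that was 1.07 in the untreated and 0.861 in the DRB table. The deposited p-value of each island with input reads equals a Poisson tail with the scaled input as an exact mean, and the deposited FDR is that p-value times the number of islands over its rank. Such a p-value leaves out the counting error of the input, which matters where the input has few reads. The significant lists were exactly the islands with an FDR under 1e-04. In 6 DRB islands the input count was 0, and there the authors' fold rests on a substitute for the 0.

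The design, the alternatives and the rule for named peaks were set before the data were examined. Named peaks were the 10 of highest fold in each list and the 10 of highest fold with no candidate island in the other condition, ties going to the wider island, together with members of fixed gene lists and METTL14. Gene annotation of hg19 was not used here, because the only gene table at hand is for GRCh38.p14. The planned analyses of genomic features, of positions along gene bodies and of gene lists were therefore not run, and peaks are named by position. Positions are 1-based, with both ends of the 0-based intervals raised by 1.

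Overlap was counted at 1 bp or more and compared with 1000 draws of DRB candidate islands matched on chromosome and width quintile. Chromosome shares were tested with exact binomial tests against the candidate islands of the same condition, and between lists with Fisher's exact test, with Benjamini-Hochberg adjustment over 24 chromosomes. Chromosome span was taken as the last candidate end. Fold intervals are exact Clopper-Pearson intervals of the IP share at a confidence level of 95%, scaled by the authors' constant. Differences in fold at a peak were tested with an exact conditional test of the 4 read counts (Fisher's noncentral hypergeometric distribution with the authors' scaling), with the reads of all DRB islands over the untreated peak summed, whatever their extent. The exact binomial test of IP against input reads was added after the data were seen. Reads are not independent molecules, so all intervals cover counting error only. With 1 table per condition, tests across islands describe these libraries and not replicate variation.

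Alternatives were a 10 times lower FDR, merging within 5 kb, leaving out chromosome Y and the mitochondrial genome, 50% reciprocal overlap, an extension by 1 kb, lists of equal length, random placement, and chromosome length as background. Added later were the binomial test, a scaling centred on islands of at least 10 kb, and leaving out islands with at least 5 times the median input density. The tests were tested on simulated data. On simulated DRB counts with no enrichment, drawn for the 67801 nuclear islands, the Poisson rule called 127 islands and the binomial test 0. With 100 islands at 2-fold and 100 at 4-fold, the binomial test recovered 2 and 70 of them, and the Poisson rule 38 and 98 with 175 false calls. These islands were drawn from all DRB candidates (medians of 21 IP and 13 input reads), and only their IP reads were raised. The significant DRB islands had medians of 18 IP and 4 input reads, so the recovery does not apply to islands with so few reads. For the 38695 untreated islands the binomial test recovered 99 and 100, with 0 false calls. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.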

Results

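Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate METTL14 on chromatin in HepG2, a human hepatocellular carcinoma cell line. METTL14 is the RNA-binding partner of the methyltransferase METTL3 in the complex that writes N6-methyladenosine on RNA. The cells carried METTL14 with an HA epitope tag, and the HA antibody was used for the immunoprecipitation (IP). The untreated condition had 2 IP libraries and 2 input libraries, and the DRB condition had 1 of each. DRB is a nucleoside analog that inhibits the kinase CDK9 and blocks transcription elongation, and was given at 100 µM for 3 h. The comparison of the conditions asks how METTL14 occupancy differs when elongation is blocked.

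The values are reads per island, an island being a run of enriched windows called by SICER, with 1 deposited table of candidate islands and 1 list of significant islands per condition. The untreated candidate islands held 15339872 IP reads and 16034656 input reads, and the DRB candidate islands held 2411436 and 2726149. Without the mitochondrial island, the untreated ones held 14495388 IP and 14661480 input reads, and the DRB ones 1977419 and 1330018. Over 7547 pairs of candidate islands that covered each other by at least 50%, the untreated input was a median 7.43 times as dense as the DRB input (quartiles 5.90 and 9.24). Replicate libraries were not separate in the files, so no value below has an error between replicates, and the intervals given are exact 95% intervals that cover counting error only. Every fold is IP reads over input reads times the authors' scaling, and every position is on hg19, named by coordinates because no gene annotation of that build was used here.

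In untreated cells METTL14 enrichment was mostly shallow. The deposited list held 1973 significant islands, 5.10% of the 38696 candidates, covering 12.4 Mb. Their median width was 4.0 kb, against 4.8 kb for all candidates. The median fold was 1.44 (quartiles 1.32 and 1.60), and 127 of them reached a fold of 2. A median of 247 IP reads and 182 input reads lay behind each. When the counting error of the input was included by an exact binomial test at the same adjusted p of 1e-04 (Benjamini-Hochberg), 312 of the 1973 passed, and all 1973 passed at an adjusted p of 0.05.

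The highest untreated fold was on chromosome X. The island at 77359201 to 77361000 had 4943 IP reads and 365 input reads, a 14.5-fold enrichment (13.1 to 16.2). On chromosome 4, 7 significant islands lay between 119604401 and 119633400, a span of 29.0 kb, with folds from 1.95 to 6.68; 3 of the 10 highest untreated folds were among them, including 6.68-fold (5.58 to 8.05) at 119626601 to 119627800. Chromosome 17 held 2 of the 10, at 18965401 to 18965800 with 7.23-fold (4.44 to 12.4) and at 19091201 to 19091600 with 3.93-fold (2.19 to 7.50). The others were on chromosome 12 at 133442801 to 133443400 (5.24-fold), chromosome 13 at 46948401 to 46948800 (4.77-fold), chromosome 1 at 148241401 to 148242200 (4.09-fold) and chromosome 10 at 103124001 to 103124800 (3.87-fold). The cells carried a METTL14 cassette, and METTL14 lies on chromosome 4. Whether vector DNA adds reads in the chromosome 4 and X regions was not tested, so they may not be METTL14 binding sites.

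Some untreated peaks were wide. Of the 76 significant islands of at least 20 kb, 64 lay on chromosomes 2, 6, 14, 16, 17 and 20, with 30 on chromosome 14. Those 6 chromosomes held 60.8% of all untreated candidates. A fold under 1.2 was found in 60 of the 76. The widest, on chromosome 14 at 43606001 to 43723000, had 12606 IP reads against 12961 input reads, a 1.04-fold enrichment. The other 16 wide islands, singled out after their values were seen, had folds of 1.2 or more, and 15 of these passed the exact binomial test at an adjusted p of 1e-04. The steepest was on chromosome 17 at 57902601 to 57927800 with 1.62-fold (1.53 to 1.71), followed by chromosome 11 at 65183401 to 65207600 with 1.57-fold (1.46 to 1.68). A 109.4 kb domain on chromosome 14 at 24047801 to 24157200 reached 1.49-fold (1.45 to 1.53), and a 59.4 kb domain on chromosome 2 at 21220801 to 21280200 reached 1.37-fold (1.32 to 1.42).

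**Figure D1:**
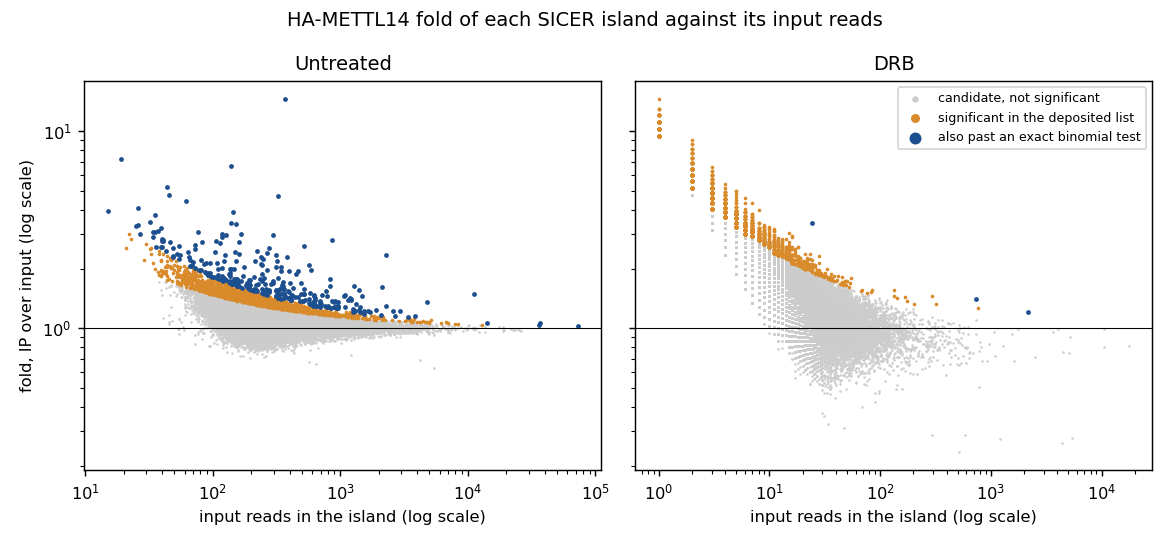
Fold of IP over input (log axis) against input reads (log axis) for each nuclear candidate island with input reads, untreated at left and DRB at right; orange marks the deposited significant islands and blue those that also pass an exact binomial test at an adjusted p of 1e-04 (312 untreated, 3 DRB). The untreated peaks had a median of 182 input reads and the DRB peaks a median of 4.

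After DRB the deposited list was longer but its islands were narrow and held few reads. It contained 3228 significant islands, 4.76% of 67802 candidates, covering 4.23 Mb. The median width was 1.0 kb, 437 islands were a single 200 bp window, and a median of 18 IP reads stood against 4 input reads. The median fold was 4.02 (quartiles 3.16 and 4.88), but 2824 islands, 87.5%, had 10 or fewer input reads. In the exact binomial test 3 of the 3228 passed at an adjusted p of 1e-04 and 5 at 0.05, while 16103 of all DRB candidates had an unadjusted p under 0.05. The 2 deposited lists were called at depths that differ by a factor of 7.43 in the input, so their lengths cannot be compared as numbers of bound sites.

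The 10 highest DRB folds, ranked by the authors' values, rested on 11 to 17 IP reads each against 0 or 1 input reads. In 6 of them the input was 0, so their rank rests on the authors' substitute for the 0. With 3 counts put in for the 0, they had values of 3.16 to 3.44, below the DRB list median of 4.02. On chromosome 11, the island at 73971601 to 73971800 had 12 IP reads and 0 input reads, so its fold has no upper bound. The exact lower bound was 2.39, and 3 counts put in for the 0 gave 3.44, where the authors' deposited value is 41.3. With 1 input read, the island on chromosome 3 at 185440001 to 185440200 had 14.6-fold with an interval of 2.29 to 611. Of these 10 peaks, 9 lay over no untreated candidate island. The 5 DRB islands that passed the binomial test at 0.05 were deeper. They lay on chromosome 10 at 42355001 to 42367000 (1.41-fold, 1.28 to 1.55), chromosome 21 at 9825401 to 9836200 (1.21-fold, 1.14 to 1.28), chromosome 4 at 49141601 to 49142800 (3.44-fold, 2.18 to 5.63), chromosome 16 at 33962201 to 33965400 (1.46-fold, 1.26 to 1.69) and chromosome 2 at 89866601 to 89882000 (1.27-fold, 1.16 to 1.40). Input density in them was 2.86 to 28.5 times the DRB median. The chromosome 4 island had 0.81-fold (0.59 to 1.12) in untreated cells, and those on chromosomes 10, 16 and 21 were significant there.

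None of the 10 highest untreated peaks lay over a significant DRB island. DRB candidate islands lay over 6 of them, with DRB folds from 0.58 to 1.01, and the other 4 had no DRB island and so no DRB fold. In the island over the chromosome X peak, DRB gave 121 IP reads and 121 input reads, 0.86-fold (0.66 to 1.12). Input density there was 3.88 times the median of all candidates in the untreated island and 10.8 times in the DRB island, and over the chromosome 4 cluster 1.46 and 2.68 times. Scaled by depth, total DRB input reads were 2.46 (1.99 to 3.03) times the untreated ones on chromosome X and 0.99 (0.85 to 1.14) times over the chromosome 4 cluster. The IP reads were 0.15 (0.12 to 0.17) and 0.25 (0.22 to 0.29) times. These totals are over unequal lengths, 11.2 kb with DRB and 20.6 kb untreated on chromosome 4, and 1.6 and 1.8 kb on X. Per kb, relative to the candidate median, DRB over untreated input was 1.83 (1.59 to 2.11) on chromosome 4 and 2.79 (2.27 to 3.42) on X. For the IP it was 0.33 (0.29 to 0.38) and 0.12 (0.098 to 0.14). The fold was lower with DRB at all 6 peaks that lay over DRB islands. Of these, only the peaks on chromosomes 13 and 10 lie outside the chromosome X and 4 regions, which may not be METTL14 binding sites. Of the 312 untreated peaks that passed the binomial test, 215 lay over DRB islands. Their median fold was 1.54 untreated and 1.05 with DRB, and the DRB value was lower in 192. The peaks were selected on their untreated values, which favors a higher untreated fold. The baselines were unlike too, since all candidates had a median fold of 1.08 untreated and 1.51 with DRB. The islands were called separately in each condition and differ in extent, so the folds do not compare the same sequence: the 600 bp peak on chromosome 4 at 119615201 was set against a DRB island of 4000 bp.

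**Figure D2:**
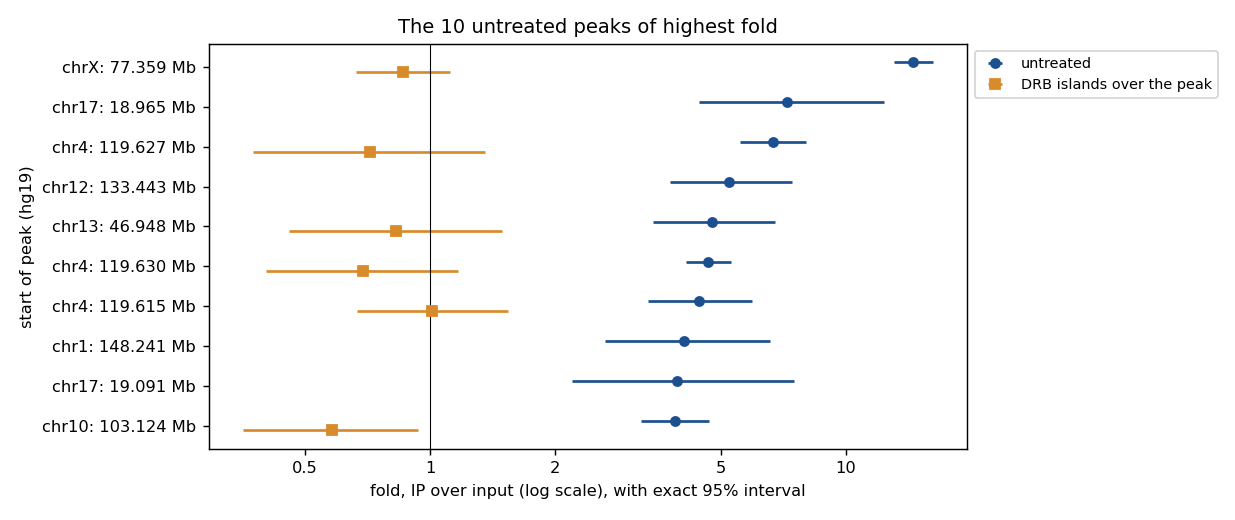
Fold of IP over input (log axis) with exact 95% intervals for the 10 untreated peaks of highest fold (circles), and for the DRB candidate islands that overlap them, which differ in extent (squares); 4 of the 10 have no DRB island and no square. The untreated folds lie between 3.87 and 14.5 and the DRB folds between 0.58 and 1.01. Peaks on chromosomes 4 and X lie in regions that may not be METTL14 binding sites.

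Most of the broad untreated domains also had lower DRB folds, which their selection on the untreated fold favors. The DRB islands there covered less than the domains, down to 1.2 kb against 20.4 kb on chromosome 13 at 91997801. Islands of the DRB table lay over all 16 domains with a fold of 1.2 or more; the median fold was 1.246 untreated and 1.02 with DRB, the DRB value was lower in 13, and in 6 the DRB interval lay wholly below the untreated one. In 1 of the 16, on chromosome 6 at 32932801 to 32953200, a DRB island was significant, with 1.103-fold over all DRB islands there (0.86 to 1.41). The domain on chromosome 17 at 57902601 had a DRB fold of 1.02 (0.87 to 1.2), and the 109.4 kb domain on chromosome 14 had 0.91 (0.85 to 0.98). On chromosome 11 at 65183401, the DRB fold of 1.13 (0.87 to 1.48) had an interval that reached the untreated one.

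Few peaks were shared by the conditions, and depth limits how many can be. Untreated reads thinned to the DRB depth kept a median of 10.4% of the untreated significant peaks by the Poisson rule. By at least 1 bp, 35 untreated significant islands, 1.77% (1.24 to 2.46), overlapped a DRB significant island, where DRB candidate islands matched on chromosome and width gave 60.9 ± 7.28 (SD over 1000 placements). The overlap did not exceed chance (one-sided permutation p = 1). It was below chance in a test of the opposite side, which was not planned (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). The same p was found with peaks extended by 1 kb (51 overlaps, 75.4 expected) and without islands of high input density (28 overlaps, 59.0 expected). Lists of equal length gave it too (5 overlaps, 31.6 expected). There the DRB list was cut to its 1973 islands of highest fold, while the draws were not matched on fold or input reads. That overlap may therefore reflect the choice of islands. The result did not hold at a 10 times lower FDR, with 10 overlaps where 11.8 were expected (one-sided permutation p = 0.36). Nor did it hold at 50% reciprocal overlap, with 13 where 11.1 were expected (one-sided permutation p = 0.786). Against random positions along the chromosomes the direction turned, with 18.9 overlaps by chance (one-sided permutation p = 0.000999). Any DRB candidate island lay under 52.3% (50.0 to 54.5) of the untreated significant islands, against 61.6% of the untreated candidates that were not significant. Of all DRB significant islands, 19.9% (18.6 to 21.3) lay over any untreated candidate island, against 53.7% of the DRB candidates that were not significant. Among those that did, 35 of 643 (5.44%) overlapped an untreated significant island, against 4.75% of the DRB islands that were not significant (Fisher's exact test, p = 0.40).

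The folds of one condition carried little information on the calls of the other. DRB islands over untreated significant peaks had a median fold of 1.22, and those over other untreated candidates 1.29. Within 10 strata of DRB IP reads the difference in mean log2 fold was -0.05 (permutation p = 0.000999, across islands, which are not independent replicates). Untreated islands over DRB significant peaks and those over other DRB candidates both had a median fold of 1.06, with a difference in mean log2 fold of 0.02 within strata (permutation p = 0.000999). Across the 35 shared peaks, Spearman's rho of the folds was -0.17 (permutation p = 0.314) and Pearson's r of the log2 folds was -0.35 (permutation p = 0.0450). Without the 7 shared peaks in islands of at least 5 times the median input density, rho was 0.24 (permutation p = 0.210) and r was 0.38 (permutation p = 0.0415).

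Peaks were not spread evenly over the chromosomes. Candidate islands of both conditions were concentrated on chromosomes 2, 6, 14, 16, 17 and 20, which held 60.8% of the untreated and 57.2% of the DRB candidates on 24.4% of the covered span. These 6 were treated as gained in HepG2. The line carries extra copies of whole chromosomes, so island density can follow copy number, which was not measured here. The expectations below rest on these candidates. Relative to its candidates, chromosome 19, the most gene-dense human chromosome, had 70 untreated peaks where 24.98 were expected, and 14.3% of its candidates were significant (exact binomial test over 24 chromosomes, Benjamini-Hochberg adjusted p = 8.88e-13). With DRB it had 22 where 31.9 were expected, 3.28% of its candidates (exact binomial test, adjusted p = 0.0937). Untreated peaks were above expectation on 15 chromosomes and below it on 2, 6, 16 and 20; DRB peaks were above on 15 and below on 2, 6, 14, 16, 17 and 20, all at an adjusted p under 0.05. The direction depends on the background: against chromosome length, chromosomes 2, 6 and 20 were above expectation and X below it in both lists.

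The chromosome shares of the lists differed between the conditions. Chromosome 19 held 3.55% of the untreated and 0.68% of the DRB peaks, an odds ratio of 0.19 (Fisher's exact test over 24 chromosomes, adjusted p = 2.15e-12). The share was lower with DRB on chromosomes 1 and 17 too, with odds ratios of 0.74 and 0.62 (Fisher's exact test, adjusted p = 0.0306 and 0.00985). It was higher on chromosomes 4, 13, 5 and 3, with odds ratios of 1.76, 1.73, 1.42 and 1.35 (Fisher's exact test, adjusted p = 4.68e-05 on chromosome 4 and 0.0372 on the others). Relative to the candidate islands, none of these 4 differed between the conditions at an adjusted p under 0.05. These tests treat islands as independent and compare the 2 lists, and were chosen after the values were seen. DRB input density was higher on chromosome 19, with a median of 8.33 reads per kb, than over all DRB candidates, with 7.0.

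**Figure D3:**
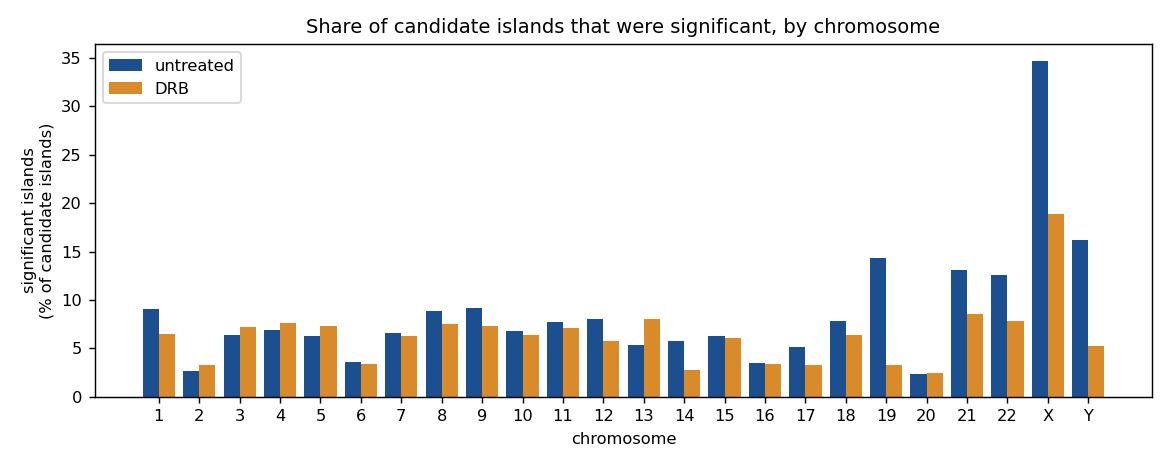
Significant islands as a percentage of candidate islands on each chromosome, untreated (blue) and DRB (orange). Chromosome 19 had 14.3% untreated and 3.28% with DRB, and chromosome X, with only 49 and 111 candidates, had 34.7% and 18.9%.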

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

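The tests in this part were chosen after the results were seen, except that of chromosome 19 among the untreated peaks that pass the binomial test. At 6 of the 10 highest untreated peaks the fold differed between the overlapping islands of the conditions by an exact test of their reads, which does not compare the same sequence because the islands differ in extent. The DRB fold over the untreated fold was 0.0592 on chromosome X at 77359201, 0.107, 0.147 and 0.229 on chromosome 4 at 119626601, 119629601 and 119615201, 0.174 on chromosome 13 at 46948401 and 0.150 on chromosome 10 at 103124001. The odds of a candidate island being called also differed between the conditions on 5 chromosomes, by a normal test of log odds ratios with Benjamini-Hochberg adjustment over 24. DRB over untreated, they were 0.731 on chromosome 1, 1.44 on chromosome 2, 0.488 on chromosome 14, 0.666 on chromosome 17 and 0.213 (0.129 to 0.350) on chromosome 19.

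The regions of high untreated fold on chromosomes 4 and X held no significant DRB island. Lower METTL14 occupancy after DRB may be the reason, since the untreated peaks that pass the binomial test, these regions included, had a median DRB fold of 1.05. All DRB candidates had a median fold of 1.51, against 1.08 untreated, so the baselines differ. With 1 DRB IP library and islands of other extent, lower occupancy cannot be told apart from a weaker immunoprecipitation. The labels say that a METTL14 cassette was introduced, and METTL14 lies on chromosome 4, but no annotation of hg19 was used to find whether the cluster is that gene. Whether vector DNA adds reads at either region was not tested, and more copies of it would raise IP and input reads alike. Input density was 3.88 (untreated) and 10.8 (DRB) times the candidate median on chromosome X and 1.46 and 2.68 times on chromosome 4, over islands of different extent. Scaled by depth, DRB over untreated total input reads were 2.46 (1.99 to 3.03) on chromosome X and 0.99 (0.85 to 1.14) on chromosome 4. The IP reads were 0.15 and 0.25 times. On chromosome 4 these totals are over 11.2 kb with DRB and 20.6 kb untreated. Per kb, relative to the candidate median, the input there was 1.83 (1.59 to 2.11) times the untreated one. Extra copies there stay open, and the labels do not say whether the inputs came from the same batch of cells.

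The DRB peaks with few input reads may arise in part from the counting error of the input, since 3 of the 3228 passed the exact binomial test. That test misses most peaks at this depth, because untreated reads thinned to it over 100 draws left a median of 18 passing islands (12 to 24) of the 312. The DRB count of 3 was still below that range. At an adjusted p of 0.05 the thinned untreated reads gave a median of 70 (47 to 93), and DRB gave 5. Depth alone thus did not bring the untreated counts as low as those of DRB. The untreated candidate islands were wider, with a median of 4.8 kb against 2.0 kb, and the effect of width was not tested. Counts simulated with no enrichment gave 127 DRB calls by the Poisson rule, far fewer than 3228, but the simulation does not include the choice of islands by their IP reads. With the scaling centred on wide islands, 2734 DRB islands were still called. That moved the constant only from 0.861 to 0.850, because the wide DRB islands already had a median fold of 1.01. It argues only against a scaling error that shows in wide islands as the whole cause. Other scalings were not tested. Binding sites gained after DRB stay open.

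The chromosome 19 share of the peaks was high in untreated cells and low with DRB, and its smaller share of the candidate islands after DRB (0.988%, against 1.27% untreated) is argued against as the whole cause, because the odds of a call relative to the candidates were 0.213 times the untreated odds. The untreated excess was not limited to peaks that need the input to be exact, since chromosome 19 held 28 of the 312 peaks that passed the binomial test, 7.09 times the number expected (exact binomial test, p = 1.47e-15). A denser DRB input on chromosome 19 could leave fewer low-input calls there: over 22 autosomes the DRB share of significant islands fell with input density (Spearman's rho = -0.71, permutation p = 0.00039; Pearson's r = -0.83; rho = -0.62 without the 2 chromosomes farthest from the median). The 22 include chromosomes 2, 6, 14, 16, 17 and 20, which were below expectation in the DRB list. Over the 16 other autosomes rho was -0.27 (permutation p = 0.317) and r was -0.64 (permutation p = 0.0407). Chromosome 19 is itself 1 of the 16, with the densest DRB input of them (8.33 reads per kb) and the lowest share (3.28%). The values over the 16 thus include the point to be explained and cannot decide, and that cause stays open. In untreated cells too, chromosome 19 had the densest input of the 16, and there the highest share. In untreated cells, where chromosome 19 input was also denser than the median (58.2 against 52.3 reads per kb), rho was 0.17 over the 22 (permutation p = 0.437) and 0.59 over the 16 (permutation p = 0.0183; r = 0.86); base composition, not tested without a genome, and a loss of METTL14 from gene-dense chromatin stay open too.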

How the results depend on the processing

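Of 34 alternatives over all results, 20 left the result on its side of the threshold or, for a count, within 1.5 times. At a 10 times lower FDR the lists held 1220 untreated and 998 DRB peaks. With the exact binomial test, added after the data were seen, they held 312 and 3. With the scaling centred on islands of at least 10 kb, the untreated list held 1257. The overlap of 35 peaks was 13 at 50% reciprocal overlap, above the 11.1 expected (one-sided permutation p = 0.324), and the same 35 exceeded the 18.9 of random placement. The share of peaks over a candidate island of the other condition was 17.2% untreated and 2.57% DRB at 50% reciprocal overlap, against 52.3% and 19.9% at 1 bp or more. With chromosome length as background, 5 chromosomes were above and 7 below expectation in the untreated list, and 5 above and 9 below in the DRB list. Directions turned as well: chromosomes 2, 6 and 20 went from below to above in both lists, X and Y from above to below in the untreated list together with 4 and 18, and 1, 13, 18, 21, 22 and X from above to below in the DRB list. At the lower FDR 7 were above in the DRB list. The Spearman correlation of the folds over shared peaks turned to 0.24 without the 7 of high input density. The causes of these changes were not tested. No paired analysis was possible because the 2 untreated replicates share 1 table and DRB has 1 IP. For the same reason no replicate could be left out. The alternatives for genomic features, gene bodies and gene lists were not run. Depth limits what can be called: in untreated reads thinned to the DRB depth, a median of 10.4% of the untreated significant peaks were still called by the Poisson rule.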

Other observations

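The tests in this part were chosen after the results were seen. Of the 312 untreated peaks that passed the exact binomial test, chromosome 19 held 28, 0.474 per Mb, chromosome 17 held 24, 0.296 per Mb, and chromosome 1 held 43, 0.173 per Mb. Relative to candidates, chromosomes 1, 8, 11, 12, 19 and X were above expectation and 2, 6 and 20 below (exact binomial test over 24 chromosomes, Benjamini-Hochberg adjusted p from 3.44e-19 to 0.0440), while chromosome 17 had 1.58 times its expected number (adjusted p = 0.0599). Leaving out the 8 islands of the chromosome 4 and X regions leaves 304.

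The passing peaks with the most reads differed widely in fold and input density. On chromosome 1 at 121482001 to 121485600, 69838 IP reads stood against 72981 input reads, 1.03-fold, at 387 times the median input density. The islands on chromosome 6 at 58772801, chromosome 10 at 42373401 and chromosome 7 at 61967201 had folds of 1.06, 1.04 and 1.06 at 97.7, 25.2 and 43.2 times the median density. The domains on chromosome 14 at 24047801 and chromosome 2 at 21220801 had folds of 1.49 and 1.37 at 1.95 and 1.53 times the median density. Among the 10 with the most IP reads were also chromosome X at 77359201 (14.5-fold, 3.88 times the median density), chromosome 21 at 9825401 (2.37-fold, 3.04 times), chromosome 18 at 105201 (1.16-fold, 10.2 times) and chromosome 6 at 64263001 (1.14-fold, 1.63 times).

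The fullest 1 Mb bin of the untreated list, on chromosome 14 starting at 43 Mb, held 10 significant islands. The fullest bin among matched draws of candidates held 5 to 11 (permutation p = 0.0240), and the number of bins with 4 or more peaks, 63, was not above the 68.1 expected (permutation p = 0.802). In the DRB list the fullest bin held 7, where draws gave 7 to 13.

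The mitochondrial genome was a single island in both tables and significant in neither. The untreated libraries had 844484 IP and 1373176 input reads there, 0.66-fold, and the DRB libraries had 434017 and 1396131, 0.27-fold. The DRB input thus held 1.02 times the untreated mitochondrial reads at a nuclear input depth 7.43 times lower, or 7.56 times as many relative to nuclear depth. Relative to nuclear depth the DRB IP held 3.06 times as many.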
